A study of Mus musculus with 52 samples.

How the data were processed

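Gene expression in 7 mouse embryonic stem (ES) cell lines was measured on 52 two-colour cDNA hybridisations, 4 for each of 13 direct comparisons between lines. Per the labels, total RNA of each line was reverse transcribed from 20 microgram and indirectly labelled with Cy3 or Cy5, and in each comparison 2 arrays carried the second-named line in Cy5 and 2 carried it in Cy3. The labels' protocol text also speaks of thawed organs and of a reference pooled from control animals. The channel labels name an ES line in both channels of every array, and these were used. The labels do not state the scanner, the image analysis, the background correction or the normalization.

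The deposited table holds log2 ratios of the 2 channels for 20794 probes, as read from the range of the values, which go to both sides of 0. Neither the log base nor the dye in the numerator is stated per the labels, so log2 is a reading used throughout. Array medians of the deposited ratios ran from -0.21 to 0.47, so the values were not centred on 0. Each array had from 17620 to 20200 measured probes. On every array a group of 20 to 174 probes shared 1 top value between 15.7 and 17.4, while the highest other value on any array was 10.7. These constant top values were treated as not measured, a choice made after the data were seen, with the kept values as an alternative. A symbol was listed for 12771 probes through the platform annotation, 8023 probes had no gene listed and none had several. The symbols were checked against the RefSeq symbol of their Entrez gene identifier and were equal for all 12771 probes. Probes with the same symbol were averaged, which gave 9030 genes, 2754 of them with more than 1 probe, and 17053 features with the unnamed probes included. The genome build of the probes is not given, so chromosomes are named and no coordinates are printed.

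Ratios were turned by the dye labels, so that each value is the second-named line minus the first-named line under the reading Cy5 over Cy3. A rule set before the data were examined would have left a comparison as it stood where arrays of opposite dye orientation correlated positively, taking the ratios as turned before deposit. The mean rank correlation of opposite orientations was above 0 in 12 of the 13 comparisons (from -0.0059 to 0.487), but it was also above 0, at 0.0758, between arrays of opposite orientation whose comparisons had no line in common. That shared part does not account for the higher values, such as 0.487 in HM-1 vs #4 (B6) and 0.220 in HM-1 vs HM-1 NT, and with each feature's mean removed 0.207 stayed in HM-1 vs #4 (B6), 0.113 in #4 (B6) vs B6NT and 0.106 in B6NT vs ZFCUMNT. Their source was not found. All arrays were turned by their labels in departure from that rule, and this choice is a reading that later checks only partly cover. A check chosen after the data were seen used the 9 triangles of comparisons, where a bias common to all comparisons cancels on the 18 sides predicted from a difference. With ratios turned the correlation of direct and indirect values was above 0 on 18 of these 18 sides (median 0.0521), and with ratios as they stand on 8 (median -0.0177). On the 9 sides predicted from a sum, where such a bias does not cancel, the median was 0.0717 turned and 0.327 as they stand. The difference sides of HM-1 vs #4 (B6) had 0.0797, 0.0712 and 0.0816 turned and 0.225, 0.171 and 0.0115 as they stand. The check therefore does not settle the orientation of HM-1 vs #4 (B6). The difference sides of HM-1 vs B6NT had 0.125 and 0.101 turned and 0.128 and 0.140 as they stand. For that comparison too the check does not decide. The orientation of each array was then checked against a prediction from the other comparisons over the 300 features with the largest predicted differences. The correlation with the prediction was above 0 on 49 of 52 arrays (median 0.216, highest 0.625), with a 95% interval above 0 on 37 arrays and below 0 on 2. Over all features the sign followed the label on fewer arrays, 43 of 52. Those that went against it were HM-1 vs #4 (B6) arrays 3 and 4, #4 (B6) vs B6NT arrays 3 and 4, #4 (B6) vs B6PGA arrays 3 and 4, B6NT vs ZFCUMNT array 2 and HM-1 NT vs ZFCUMNT arrays 1 and 3, so the 3 comparisons named above, whose opposite orientations stayed positively correlated, are among them. The overall sign stays open: there was no probe for Hprt or Xist, and of the Y-linked genes Kdm5d was too variable and Zfy1 too close to 0 to settle it. Signs are therefore given as positive or negative, and if the deposited ratio is Cy3 over Cy5, every sign turns at once.

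The 13 comparisons were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient per comparison and a dye term for each feature, so that all arrays shared 1 estimate of the spread. A feature was tested in a comparison if at least 3 of its 4 arrays measured it in both dye orientations. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Chance alone gives an unadjusted p under 0.05 to a share of about 0.05 of the features tested. The mean of HM-1 vs HM-1 NT and #4 (B6) vs B6NT, called the shared NT contrast, and the difference between them were tested in the same fit. Replicates are hybridisations. The labels do not say that the 4 arrays of a comparison came from separate cultures or RNA extracts, so all p-values measure the spread between hybridisations only.

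Before the data were examined, 25 gene lists were fixed (lineage and cell type markers, imprinted genes, chromatin factors, metabolic pathways, stress responses, cell cycle genes and ribosomal proteins). Of these, 22 had at least 3 measured genes and were tested in 10 contrasts, 220 tests in all, with limma's camera on the moderated t of each contrast, a preset correlation of 0.01, and adjustment over the lists of a contrast. The estimated inter-gene correlation, fry, arrays averaged per comparison and removal of a lowess trend of the ratios with residual spread were alternatives. The rule for named genes was also fixed beforehand. In HM-1 vs HM-1 NT, #4 (B6) vs B6NT, #4 (B6) vs B6PGA and PDCUMNT vs ZFCUMNT it takes up to 10 genes with the largest ratios in each direction among those past the threshold with 1 sign on all measured arrays. In the other comparisons it takes 3, and list members past the threshold are named as well.

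The fit was tested on simulated data made from HM-1 vs HM-1 NT (16127 features, 200 of them changed). Of changes of 1 on the log2 scale 15% were recovered, of changes of 2 60%, with median estimates of 1.03 and 2.02 and 2 unchanged features among 77 calls; the other 12 comparisons gave 0 calls. A list shifted in the simulation had a camera p of 3.8e-05 and an unshifted list 0.868. The orientation check, tried on PDCUMNT vs ZFCUMNT, found the 1 array that had been reversed and no other. For this trial differences between all lines were simulated in every feature. On the real arrays of that comparison the correlation with the prediction was only 0.054 to 0.151, with an interval above 0 on array 1 alone. The trial therefore does not show that the check would find a reversed array in the real data. All simulated arrays had independent noise, with 1 spread per feature. They hold neither the unequal spread of the real arrays nor their unexplained correlations. The simulation therefore does not show how many false calls the real data hold.

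Alternatives set beforehand were: array medians subtracted; arrays scaled to equal spread; no dye term; each comparison fitted alone; features measured on all 4 arrays; no filter; probes tested singly; a fold of at least 1.5 asked as well; a model with 1 coefficient per line, also with the comparison as a random block and on arrays averaged per comparison; the replicate number as a block; and each array left out in turn. Chosen after the data were seen were: top values kept; ratios not turned; HM-1 NT vs ZFCUMNT with arrays 1 and 3 exchanged or left out; the line model without that comparison; the lists with the trend removed; and limma's array weights. The number of arrays limits the precision of every value.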

Results

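The 7 lines were HM-1, a mouse ES line used for gene targeting, HM-1 NT, #4 (B6), B6NT, B6PGA, PDCUMNT and ZFCUMNT. Per the series description the lines differ in the source of the donor nuclei, and cumulus cells, the somatic cells around the oocyte, were the source for a pair of lines that differ in cloning method. The description does not name that pair, and the labels do not spell out NT, B6, PGA, PD or ZF. Each comparison had 4 arrays, and between 15067 and 16493 features were tested in it. Values are log2 ratios, second-named line minus first-named line, with the standard error of the fit. The deposited ratios do not name the numerator dye, so the overall sign is open. Over the 300 features with the largest predicted differences, 2 arrays of HM-1 NT vs ZFCUMNT had an interval wholly below 0, against their labels. Over all features only 43 of 52 arrays followed their label. The others included arrays of HM-1 vs #4 (B6), #4 (B6) vs B6NT, #4 (B6) vs B6PGA and B6NT vs ZFCUMNT. Signs of genes and lists in these comparisons rest on the labels, and the orientation of HM-1 vs #4 (B6) was not settled. The triangles of comparisons did not settle that of HM-1 vs B6NT either. For HM-1 vs HM-1 NT it also stays in doubt. Arrays of opposite orientation correlated at 0.220 there from a source not found, and the intervals of its arrays 2 and 4 included 0.

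The genes called between HM-1 and HM-1 NT included Dppa3, Hmgcs1, H4c8 and Lefty2. Dppa3 (Entrez gene 73708, chromosome 6), which protects the maternal genome of the early embryo from demethylation, had a value of 2.18 ± 0.35 (SE, n = 4 arrays, adjusted p = 1.2e-03). Hmgcs1, an early enzyme of cholesterol synthesis, was at 1.48 ± 0.32, and Igfbp3, which binds insulin-like growth factors, at 1.55 ± 0.32. The histone H4 gene H4c8 (Entrez gene 69386, chromosome 13) was at -1.28 ± 0.15 (adjusted p = 2.7e-06) and Lefty2 (Entrez gene 320202, chromosome 1), a secreted inhibitor of Nodal signalling, at -1.08 ± 0.25 (adjusted p = 0.039). Among 16127 features 41 passed, 27 positive and 14 negative. The other named genes were Cfap126 (2.51 ± 0.51), a ciliary gene, Btg3 (2.47 ± 0.55), a brake on proliferation, the desmosomal plaque gene Pkp1 (2.31 ± 0.51), Thnsl1 (2.27 ± 0.46), Bex1 (1.25 ± 0.25), the exon junction gene Rbm8a (1.17 ± 0.19) and the proteasome gene Psma2 (1.06 ± 0.25). Shkbp1, measured on 3 arrays, was at -2.83 ± 0.49. On single arrays Btg3 was at 0.475 and 0.36 in one dye orientation and at 4.46 and 4.59 in the other. Thnsl1 ran from 0.297 to 6.395.

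In HM-1 vs HM-1 NT 10 of the 22 lists were called, all 10 with positive values, against a median of -0.05 over all features. The pluripotency list had a median of 0.15 over 26 measured genes (camera adjusted p = 4.4e-04), with Dppa3 the 1 member called and 25 not; adjusted over the list alone 2 passed, the other being Trim28 at 0.82 ± 0.23. Markers of fibroblasts, used here for feeder cells, moved the same way: their median was 0.36 over 27 genes (adjusted p = 3.3e-06), with 22 values positive, none of them called over all features and 4 adjusted over the list alone (Timp3 0.66, Col1a1 0.74, Col5a1 0.74 and Vim 0.61). Ribosomal protein genes had a median of 0.22 over 55 genes (2.5e-09), cell cycle genes 0.35 over 33 (2.0e-06), oxidative phosphorylation genes 0.31 over 45 (2.0e-06), cholesterol synthesis genes 0.23 over 10 (3.3e-03), heat shock and unfolded protein genes 0.28 over 25 (1.4e-03), chromatin and DNA methylation factors 0.17 over 31 (0.017), trophectoderm markers 0.25 over 10 (0.030) and interferon and antigen presentation genes 0.13 over 17 (0.022). The last of these lost its call with an estimated correlation (adjusted p = 0.053). The chromatin, trophectoderm and interferon lists each had a negative median on 1 of the 4 arrays. The count of 41 fell to 19 without array 3 (5 positive, 14 negative) and to 24 without array 4 (6 and 18), so its excess of positive calls rests on these arrays (without array 2 it was 53 and 4), and was 0 when the comparison was fitted alone, with 1033 features at an unadjusted p under 0.05 in the joint fit. With array weights it rose to 197, and these included all 41.

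#4 (B6) and B6NT differed in regulators of the undifferentiated state. Dppa5a (Entrez gene 434423, chromosome 9), an RNA-binding protein of undifferentiated cells, was at 2.12 ± 0.20 (SE, n = 4 arrays, adjusted p = 4.2e-09), Lefty2 at 2.25 ± 0.25 (1.2e-07), Klf4 (Entrez gene 16600, chromosome 4), a pluripotency transcription factor, at 1.01 ± 0.18 (1.7e-03), and the zinc finger gene Sall1 at 1.62 ± 0.35 (0.021). The matrix genes Col1a1 (-1.32 ± 0.24) and Timp3 (-1.15 ± 0.19) had negative values. Of 15914 features 39 passed, 23 positive and 16 negative. Further positive named genes were the mitochondrial ribosome gene Mrps18a (3.02 ± 0.35, 3 arrays), the chemokine Ccl3 (2.32 ± 0.49), Rrp1b (1.80 ± 0.38), the nucleotide synthesis gene Prps1 (1.45 ± 0.26), the importin Ipo11 (1.24 ± 0.29), which turned negative with top values kept, and the small heat shock gene Hspb1 (1.06 ± 0.21). Further negative ones were Ogfod3 (-3.51 ± 0.72, 3 arrays), Arhgap45 (-3.08 ± 0.53), the sperm surface gene Adam3 (-3.01 ± 0.47, 3 arrays), the G protein gene Gna11 (-2.39 ± 0.51, 3 arrays), the thyrotropin receptor Tshr (-2.29 ± 0.32, 3 arrays) and Mta3 (-2.16 ± 0.50). All 18 named genes stayed past the threshold with array weights. On single arrays Ccl3 ran from 0.004 to 4.55.

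The pluripotency list in #4 (B6) vs B6NT had a median of 0.22 over 26 genes (adjusted p = 1.5e-09), with 21 positive values, 2 members called and 5 adjusted over the list alone, among them Jarid2 at 0.71 ± 0.21 and Rif1 at 0.83 ± 0.29. Primed epiblast markers had a median of 0.38 over 7 genes (7.1e-04), with Lefty2 the 1 member called. Their medians on single arrays were 0.24 and 0.75 in one dye orientation and -0.35 and -0.14 in the other. Fibroblast markers went the other way, with a median of -0.23 over 25 genes (1.8e-07), 20 negative values and 2 members called, both also adjusted over the list alone. The median on array 2 was 0.04. Interferon and antigen presentation genes had a median of -0.33 over 16 genes (0.043; adjusted p = 0.11 with an estimated correlation) and no member called. Asf1a (0.94 ± 0.17), a histone chaperone, Hspb1 and Rpl39 (0.82 ± 0.16) passed in lists that were not called. Fitted alone the comparison gave 0 calls, and with arrays scaled to equal spread it gave 223. In the joint fit 716 of 15914 features had an unadjusted p under 0.05, no more than the share of 0.05 that chance gives.

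Both comparisons of a line with the NT line of the same name were joined in the shared NT contrast, which rests on 8 arrays with no array or line in common. Dppa5a was at 1.25 ± 0.14 (SE, n = 8 arrays, adjusted p = 7.5e-07), Dppa3 at 1.42 ± 0.25 (2.6e-03) and Mrps18a at 1.54 ± 0.23 (7 arrays, 6.3e-04). H4c8 was at -0.65 ± 0.11, the retinoic acid binding gene Crabp1 at -0.96 ± 0.20 and Tshr at -1.28 ± 0.21 (7 arrays). Klf4 (0.59 ± 0.13), Asf1a (0.55 ± 0.12), Hspb1 (0.76 ± 0.15) and Rpl39 (0.52 ± 0.11) also passed. Most of these means were carried by 1 side: in HM-1 vs HM-1 NT Dppa5a was at 0.38, Klf4 at 0.17, Asf1a at 0.17, Hspb1 at 0.46, Rpl39 at 0.22 and Mrps18a at 0.06, none of them called, while Dppa3 was at 0.67 and not called in #4 (B6) vs B6NT. Likewise H4c8 was at -0.01 in #4 (B6) vs B6NT and Tshr at -0.27 in HM-1 vs HM-1 NT, neither of them called. Crabp1 was at -0.92 and -1.0 and called in neither. Of 15227 features 23 passed, 17 positive and 6 negative. The pluripotency list had the clearest shift, with a median of 0.23 over 26 genes (adjusted p = 1.4e-11), 21 positive values, 3 members called and 5 adjusted over the list alone. Ribosomal protein genes (median 0.20, 55 genes, 5.2e-07), cell cycle genes (0.21, 28 genes, 2.4e-05), heat shock genes (0.16, 24 genes, 1.1e-03), oxidative phosphorylation genes (0.13, 42 genes, 2.0e-03), cholesterol synthesis genes (0.17, 9 genes, 7.5e-03) and chromatin factors (0.09, 29 genes, 0.010) were called as well, all positive. Unlike the pluripotency list, called in both comparisons, these lists were called in HM-1 vs HM-1 NT but not in #4 (B6) vs B6NT. The fibroblast list, called with opposite signs in the separate comparisons, had a median of -0.01 over 25 genes (0.94). The pluripotency list was also called without a line named NT, in HM-1 vs #4 (B6) (median -0.17) and #4 (B6) vs B6PGA (0.25). It was not called in HM-1 vs B6NT. Among the 13 single comparisons Dppa5a and Klf4 passed only in some with #4 (B6), and H4c8 only in those with HM-1. The shared contrast therefore does not separate a change common to NT lines from traits of #4 (B6) or HM-1.

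In the NT comparisons Lefty2 passed with opposite signs. No feature passed with the same sign in both, but independent lists would share only 0.039 positive and 0.015 negative features, so lists of this size do not show how much was shared. Across 15227 features, which are not independent replicates, the Pearson correlation of the 2 sets of values was -0.0061. The same difference measured directly and indirectly reached a median of 0.0609. The test of the difference (HM-1 vs HM-1 NT minus #4 (B6) vs B6NT) called 30 features, 18 positive and 12 negative, with Adam3 at 3.86 ± 0.62 (7 arrays), Ccdc80, a secreted matrix protein, at 3.18 ± 0.72 and Igfbp3 at 2.51 ± 0.46. The negative named genes were Lefty2 (-3.32 ± 0.35), Shkbp1 (-3.31 ± 0.65, 7 arrays) and Mrps18a (-2.96 ± 0.46, 7 arrays). The shared count of 23 fell to between 8 and 14 without any single array except array 4 of #4 (B6) vs B6NT, which left 17; without array 3 of that comparison the difference gave 18. Its excess of positive calls levelled without array 3 or 4 of that comparison (9 and 9, 15 and 15) and turned without array 3 or 4 of HM-1 vs HM-1 NT (10 and 12, 9 and 15). Fitted alone, the shared contrast gave 0 calls and the difference 1. In the joint fit 808 and 788 of 15227 features had an unadjusted p under 0.05, near the share of 0.05 that chance gives.

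**Figure D1:**
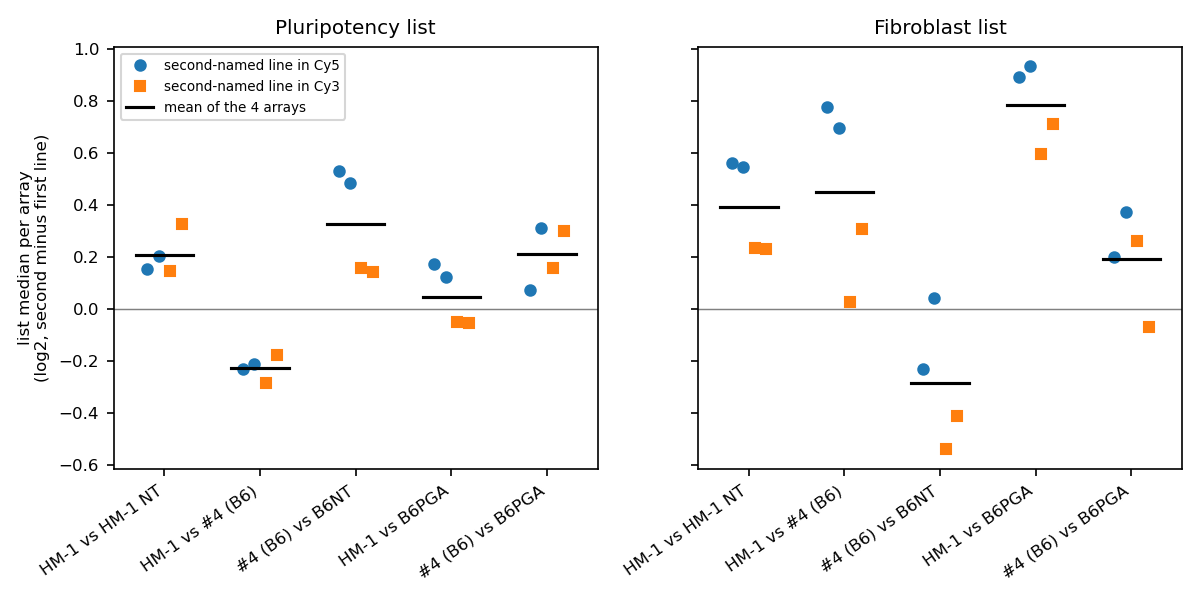
Median log2 ratio (y axis, second-named minus first-named line) of the pluripotency and fibroblast lists on each array of 5 comparisons (x axis); circles and squares are the dye orientations and bars the mean of the 4 arrays. In HM-1 vs B6PGA the fibroblast medians lay between 0.60 and 0.94, while the pluripotency medians lay between -0.06 and 0.17.

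#4 (B6) vs B6PGA set a pair of lines labelled B6 against each other and again separated the genes Sall1 (2.80 ± 0.35, SE, n = 4 arrays, adjusted p = 3.3e-06), Dppa5a (1.81 ± 0.20, 1.9e-07), Klf4 (1.81 ± 0.18, 2.1e-08) and Lefty2 (1.74 ± 0.25, 2.1e-05). Rif1, a telomere and replication timing factor, was at 1.14 ± 0.29, the imprinted gene Nnat at 1.93 ± 0.38 and the caudal homeobox gene Cdx2 at 1.13 ± 0.28. Of 15535 features 189 passed, 99 positive and 90 negative (64 and 96 without array 3, 72 and 87 without array 4). Further positive named genes were the junction gene Jam2 (2.46 ± 0.30), Tada3 (2.63 ± 0.42), Mrpl16 (2.23 ± 0.38), the lipid carrier Fabp5 (2.30 ± 0.48), Bhlhb9 (2.58 ± 0.55), Mmp3 (2.60 ± 0.61), Il12rb1 (2.09 ± 0.41, 3 arrays) and Rpl36al (1.92 ± 0.49). Negative named genes were Retreg2 (-3.88 ± 0.98), Ces1c (-3.25 ± 0.73), Mbtd1 (-3.09 ± 0.50), Sh3bgrl (-2.66 ± 0.52), Tssk2 (-2.64 ± 0.56), Prkra (-2.58 ± 0.59), Ccny (-2.40 ± 0.45), Uchl1 (-2.32 ± 0.58) and Znrd1 (-2.02 ± 0.27), each on 3 arrays, and growth hormone, Gh (-2.40 ± 0.54), on 4. The pluripotency list was the only list called (median 0.25 over 26 genes, adjusted p = 6.8e-05, 3 members called and 4 adjusted over the list alone). The fibroblast list had a median of 0.16 over 25 genes (0.054; adjusted p = 0.31 with an estimated correlation), with Lox called at 0.79 ± 0.20. Rpl39 (0.97 ± 0.16) and Rpsa (0.72 ± 0.16) were positive, Asf1a was at 0.72 ± 0.17 and the respiratory chain gene Cox7a2 at -1.44 ± 0.36. With array weights 98 features passed, 14 of the 20 genes with the largest ratios among them; Mmp3, Il12rb1, Rpl36al, Ces1c, Tssk2 and Uchl1 did not. Cdx2 turned to -0.06 when its probes were tested singly.

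PDCUMNT vs ZFCUMNT compared the lines whose names both hold CUM. The largest positive values were those of Fbxw17 (4.47 ± 0.68, 3 arrays, adjusted p = 4.4e-04), Arid3a (3.92 ± 0.77, 3 arrays) and Rnf112 (2.73 ± 0.59, 3 arrays), and Bpgm, an enzyme of red cell glycolysis, was at 2.58 ± 0.41 (SE, n = 4 arrays, 4.4e-04). Sh2d2a (2.52 ± 0.56, with 1 of its probes of the opposite sign), Nupr1l (2.52 ± 0.52, 3 arrays), Wdr54 (2.21 ± 0.49, 3 arrays), Mios (2.19 ± 0.51), the galectin Lgals8 (2.18 ± 0.55), Irs3 (2.17 ± 0.39, 3 arrays) and the interferon-induced gene Ifi35 (1.14 ± 0.26) were positive as well. Spsb2 (-1.92 ± 0.46), the apoptosis inhibitor Xiap (-1.62 ± 0.41, 3 arrays), Frmd8 (-1.53 ± 0.36), Hils1 (-1.38 ± 0.35) and Dand5 (-1.10 ± 0.27), an inhibitor of Nodal and BMP signals, were negative. None of the 22 lists was called by camera, where 0 had an unadjusted p under 0.05 (fry called 1), and the pluripotency list had a median of 0.02 over 26 genes (0.76). Of 15469 features 118 passed, 91 positive and 27 negative. The count was 131 without array 3, 297 without array 4 and 18 with arrays scaled to equal spread. The median of all features was 0.11, and subtracting array medians, a shift of -0.10, left 67 calls, 37 positive and 30 negative. With array weights 14 features passed, among them Fbxw17, Bpgm, Nupr1l and Irs3, while the other 11 of the 15 genes with the largest ratios did not.

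In HM-1 vs #4 (B6), Zfp42 (Entrez gene 22702, chromosome 8), also known as Rex1 and a marker of the naive state, was at -2.85 ± 0.41 (SE, n = 4 arrays, adjusted p = 1.9e-04). Dppa5a (-1.41 ± 0.20), Klf4 (-0.82 ± 0.18), Sall1 (-1.78 ± 0.35), Lefty2 (-1.29 ± 0.25) and Rrs1, a ribosome assembly factor (-3.37 ± 0.58, 3 arrays), were negative too. On single arrays Rrs1 ran from -7.01 to -0.472. The enkephalin precursor Penk (1.89 ± 0.29), Kbtbd8 (2.40 ± 0.54), Rasgrp1 (1.60 ± 0.36) and the intermediate filament gene Vim (1.04 ± 0.21) were positive. The pluripotency list had a median of -0.17 over 25 genes (adjusted p = 6.3e-08, 3 members called; adjusted over the list alone 6 negative and 1 positive), and the fibroblast list 0.43 over 26 genes (2.9e-09), with Vim the 1 member called and 2 adjusted over the list alone. Primed epiblast markers had a median of -0.13 over 6 genes (0.045; adjusted p = 0.12 with an estimated correlation). Of 16410 features 36 passed, 13 positive and 23 negative. The count was 19 without array 1, 14 without array 2 (7 positive, 7 negative) and 49 without array 3 (7 and 42), and 91 with array weights, of which 57 were positive and 34 negative.

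In HM-1 vs B6NT Zfp42 was at -2.90 ± 0.41 (SE, n = 4 arrays, adjusted p = 1.3e-04), H4c8 at -1.10 ± 0.15 and Dhcr7 (Entrez gene 13360, chromosome 7), the last enzyme of cholesterol synthesis, at -1.89 ± 0.39. The X-linked homeobox gene Rhox5 (2.10 ± 0.37), the imprinted zinc finger gene Peg3 (1.84 ± 0.34), Gatad1 (1.70 ± 0.38), Hspb1 (1.03 ± 0.21) and Rpl39 (0.72 ± 0.16) were positive. No list was called by camera or fry, 6 had an unadjusted camera p under 0.05 and 4 were called on arrays averaged per comparison; the pluripotency list had a median of 0.08 and a mean of -0.01 over 25 genes (adjusted p = 0.89). Of 16493 features 28 passed, 21 positive and 7 negative, and the count was 16 without array 3 (8 and 8), 47 without array 1 and 241 with array weights (149 positive, 92 negative).

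HM-1 vs B6PGA held the list median farthest from 0 in the 220 list tests. All but 1 of 27 measured fibroblast markers were positive, with a median of 0.90 (camera adjusted p = 9.0e-30); 8 were called and 14 passed adjusted over the list alone. Those called were the collagens Col3a1 (1.64 ± 0.25, SE, n = 4 arrays), Col1a2 (1.20 ± 0.26), Col1a1 (1.18 ± 0.24) and Col6a2 (1.05 ± 0.23), the collagen crosslinking enzyme Lox (1.31 ± 0.20), Fbln2 (1.10 ± 0.18), fibronectin, Fn1 (0.99 ± 0.25), and Vim (0.97 ± 0.21). Primitive endoderm markers had a median of 0.18 over 17 genes (6.0e-03), with Ttr (1.32 ± 0.25), Sparc (1.25 ± 0.27) and Apoe (1.44 ± 0.35) called and a median of -0.27 on array 3. Interferon and antigen presentation genes (0.23, 17 genes, 0.014; B2m 1.35 ± 0.32 and Ifitm3 1.26 ± 0.29 called), heat shock genes (0.24, 24 genes, 6.6e-03; Hsph1 2.19 ± 0.51 called) and targets of p53 (0.20, 17 genes, 0.012; none called, and 2 adjusted over the list alone, Cdkn1a 0.84 and Btg2 1.02) were positive beside them. The interferon and heat shock lists each had a negative median on 1 array. The pluripotency list was not called (median -0.02 over 25 genes, 0.97), though Zfp42 was at -2.14 ± 0.41. Named by size were Lypla2 (3.63 ± 0.62), Penk (2.59 ± 0.29) and Sectm1a (2.56 ± 0.55), and on the negative side Cox10 (-3.51 ± 0.67, 3 arrays), the RNA methylation gene Mettl14 (-2.71 ± 0.52, 3 arrays) and Dhcr7 (-2.47 ± 0.39). On single arrays Lypla2 ran from 0.417 to 8.791 and Sectm1a from 0.005 to 6.054. Cox10 ran from -6.532 to -0.475, and Mettl14 had -6.432, -0.508 and -0.947. The standard errors of these genes thus understate the spread between these arrays. Rhox6 (2.42 ± 0.53) and Rpl39 (0.86 ± 0.16) also passed. Of 16191 features 80 passed, 63 positive and 17 negative, but the excess of positive calls rests on single arrays (34 and 41 without array 3, 38 and 30 without array 4). With array weights 319 passed, 176 positive and 143 negative, all 80 among them.

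HM-1 vs PDCUMNT gave 180 calls among 15842 features, 88 positive and 92 negative. The balance moved to 53 and 164 without array 3, 55 and 93 without array 4, and 105 and 77 with array medians subtracted. Bnip3 (4.06 ± 0.70, SE, n = 3 arrays, adjusted p = 1.5e-03), a hypoxia-induced mitophagy receptor, Zdhhc19 (4.63 ± 0.97, 3 arrays) and Inf2 (2.86 ± 0.58) had the largest positive values, and Ctnnd2 (-4.31 ± 0.72), Pqlc3 (-3.88 ± 0.96) and 4930524B15Rik (-3.16 ± 0.73) the largest negative ones, each on 3 arrays. Dhcr7 was at -3.12 ± 0.39, Zfp42 at -2.53 ± 0.41 and Lefty2 at -1.91 ± 0.25, while Pou5f1, the pluripotency factor Oct4, was at 0.87 ± 0.22, Peg3 at 1.44 ± 0.34, Hmgcs1 at 1.34 ± 0.32 and the neural gene Hes5 at 2.21 ± 0.55. Oxidative phosphorylation genes had a median of 0.33 over 45 genes (5.2e-05, none called, 5 adjusted over the list alone) and cell cycle genes 0.29 over 33 (8.6e-04), with Plk1 called at 1.37 ± 0.33. Glycolysis and hypoxia genes had a median of 0.15 over 25 genes (0.031), with Bnip3 and, of the opposite sign, the glucose transporter Slc2a3 (-1.16 ± 0.28) called; with fry that list had the opposite direction (adjusted p = 0.694). Its median on array 3 was -0.18. The p53 target list had a median of -0.16 (0.59) and the pluripotency list 0.08 over 26 genes (0.097), with 1 member called in each direction. Chac1 (-1.60 ± 0.42), Hspb1 (0.82 ± 0.21), Bst2 (0.87 ± 0.18), Rpl7 (0.90 ± 0.22), Rpl37a (0.79 ± 0.19) and the X-linked translation factor Eif2s3x (1.56 ± 0.40) passed in lists that were not called. With array weights 4930524B15Rik was no longer past the threshold.

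In HM-1 vs ZFCUMNT Lefty2 was at -2.51 ± 0.25 (SE, n = 4 arrays, adjusted p = 4.9e-09), Dhcr7 at -2.54 ± 0.39, Zfp42 at -2.44 ± 0.41 and H4c8 at -1.20 ± 0.15. Fcrls (3.68 ± 0.69, 3 arrays), Peg3 (1.73 ± 0.34) and Rbm8a (1.14 ± 0.19) were positive. Paternally expressed imprinted genes had a median of 0.33 over 13 genes (5.3e-04), with Peg3 called and Nnat at 1.37 ± 0.32 passing adjusted over the list alone. Fibroblast markers (0.10, 27 genes, 8.3e-03), interferon genes (0.24, 15 genes, 5.1e-03), chromatin factors (0.09, 30 genes, 0.012) and heat shock genes (0.23, 23 genes, 0.017; adjusted p = 0.075 with an estimated correlation) were called as positive with no member called. On single arrays the fibroblast medians were 0.36 and 0.56 in one dye orientation and -0.03 and -0.19 in the other. The heat shock medians were negative on 2 of 4 arrays, and the interferon and chromatin medians on 1 each. The primed epiblast list was called as negative (6 genes, 5.1e-03), but its median of -0.06 equals that of all features. Lefty2 was the 1 member called, and the list was not tested without it. Dnmt3a (0.95 ± 0.32) was positive and passed adjusted over the list alone. With fry 2 of the 6 lists stayed called, primed epiblast and paternally expressed imprinted genes. Of 15906 features 16 passed, 6 positive and 10 negative (9 and 8 without array 2, 10 and 9 with array medians subtracted). With array weights 308 passed, including all 16.

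B6NT vs HM-1 NT gave 158 calls among 15221 features, 66 positive and 92 negative. Dhcr7 was at 2.88 ± 0.39 (SE, n = 4 arrays, adjusted p = 3.3e-05), the synaptic gene Syn2 at 3.31 ± 0.66 (3 arrays) and the ion transport regulator Fxyd4 at 3.16 ± 0.70. Zfp42 (2.24 ± 0.41) was positive, and Peg3 (-1.97 ± 0.34) and Lefty2 (-1.64 ± 0.25) were negative, as were the peroxisome gene Pex11a (-3.12 ± 0.80, 3 arrays), Tmem115 (-2.75 ± 0.59, 3 arrays) and Cyth4 (-2.32 ± 0.41). The count was 96 without array 1 and 97 without array 4. B6NT vs ZFCUMNT gave 20 calls among 16108 features, 15 positive and 5 negative, led by Lefty2 at -2.65 ± 0.25 (1.8e-09). The respiratory chain gene Ndufa13 (2.51 ± 0.45, 3 arrays), the kinase gene Map3k14 (2.13 ± 0.45) and the coatomer gene Copz1 (1.83 ± 0.33) were positive. With array medians subtracted 9 positive and 10 negative features passed. The count was 9 without array 3, 12 without array 4, 34 without array 1 and 68 with array weights.

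Averaged over their 4 arrays, the remaining comparisons with ZFCUMNT had the widest spread of ratios (#4 (B6) 0.948, HM-1 NT 0.900). Single arrays were narrower, down to 0.695 and 0.732. In #4 (B6) vs ZFCUMNT 147 of 15716 features passed, 104 positive and 43 negative, with Spata2l (4.83 ± 0.76, SE, n = 3 arrays, adjusted p = 6.6e-04), Hmbox1 (4.20 ± 0.80, 3 arrays), the homeobox gene Irx3 (4.16 ± 0.95, 3 arrays) and Dppa5a (2.04 ± 0.20, 4 arrays) positive. Fez1 (-3.20 ± 0.82, 3 arrays), the citrate cycle gene Ogdh (-2.60 ± 0.49) and Phyhip (-2.52 ± 0.53) were negative. Of the 6 genes with the largest ratios only Spata2l stayed past the threshold with array weights, which left 51 calls; single arrays left out gave 40 (array 1, 20 positive and 20 negative), 72 (array 2), 374 (array 3) and 334 (array 4). In HM-1 NT vs ZFCUMNT 44 of 15067 features passed, 17 positive and 27 negative, with the membrane repair gene Dysf (3.62 ± 0.65, 3 arrays), the fatty acid elongase Elovl7 (3.60 ± 0.59, 3 arrays) and Slc35e3 (2.46 ± 0.50) positive and the GABA transporter Slc6a13 (-3.33 ± 0.67), 2900026A02Rik (-2.93 ± 0.44, 3 arrays) and the RNA editing enzyme Adar (-2.77 ± 0.65) negative. The arrays labelled 1 and 3 of that comparison ran against the prediction from all others (correlations of -0.199 and -0.130); without both, 221 features passed, and without array 1, 3 or 4 alone 83, 76 or 72. With the orientation of both exchanged 63 passed, and all 6 genes named here took the opposite sign, 2900026A02Rik with a call (2.45, adjusted p = 0.011). Adar and Slc6a13 did not pass with array weights, which left 18 calls.

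**Figure D2:**
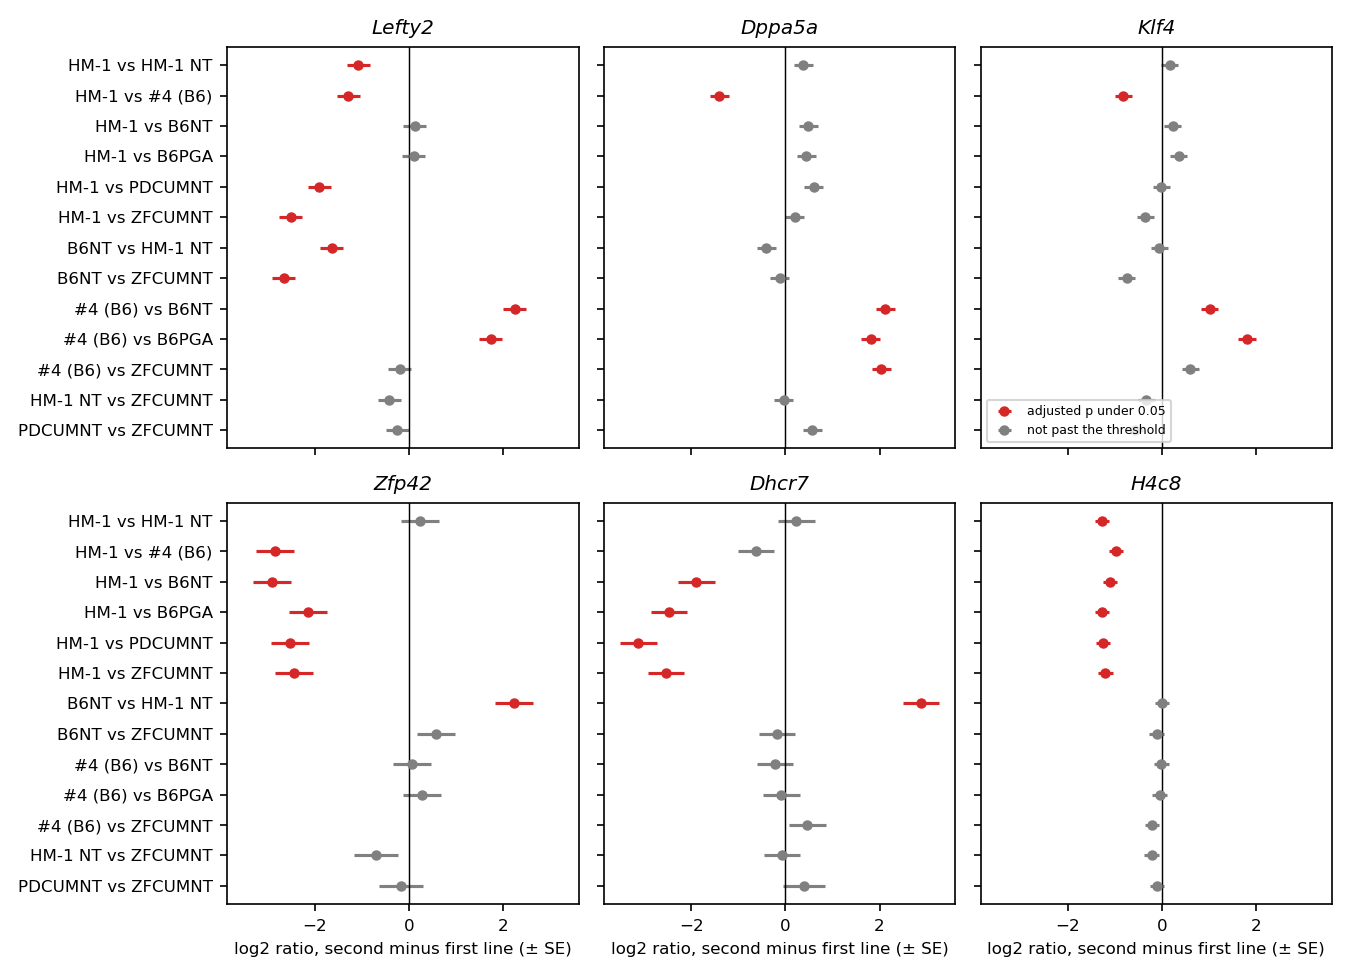
Log2 ratio with its standard error (x axis, second-named minus first-named line) of 6 genes in the 13 comparisons (y axis), in red where the adjusted p was under 0.05. H4c8 was called in all 6 comparisons with HM-1, at -1.28 to -0.98, and in none of the other 7.

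Only the X chromosome stood apart in a test of each chromosome in each comparison (camera, 260 tests, adjusted together). Its features had a median 0.24 above that of all features in HM-1 vs B6NT (222 features, adjusted p = 2.9e-07) and 0.22 above in HM-1 vs B6PGA (220 features, 9.2e-04). They were at -0.32 relative to all features in B6NT vs HM-1 NT (202 features, 4.9e-05) and at -0.15 in B6NT vs ZFCUMNT (223 features, 9.2e-05). In the other comparisons with B6NT or B6PGA, #4 (B6) vs B6NT and #4 (B6) vs B6PGA, the shift was 0.05 (adjusted p = 0.9996 in both). The sign on single arrays does not set the 4 apart. X-linked minus autosomal medians had 1 sign on all 4 arrays in 10 of the 13 comparisons, #4 (B6) vs B6NT among them.

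**Figure D3:**
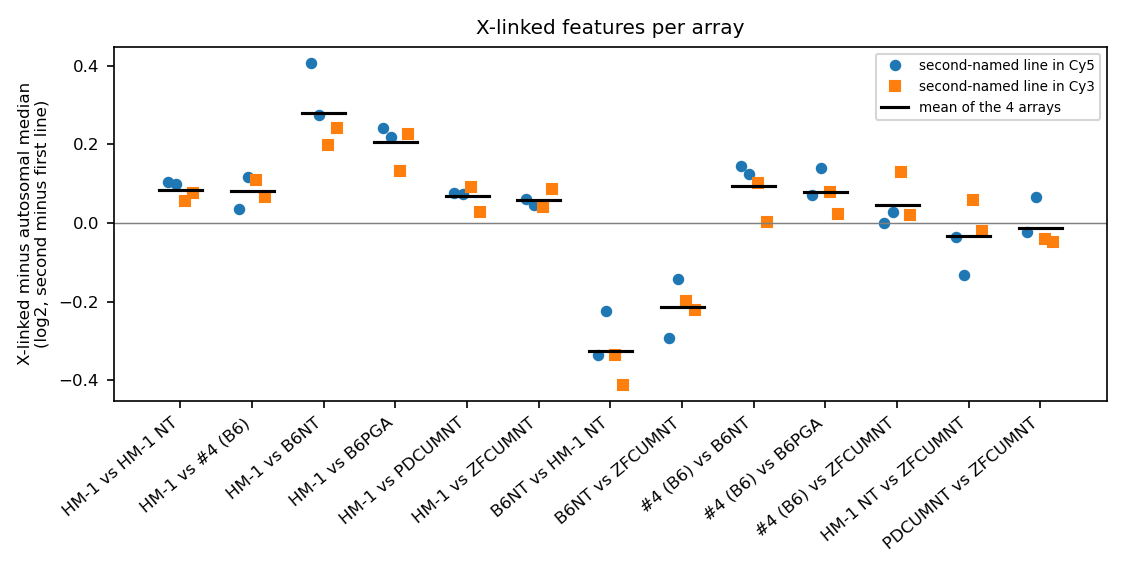
Median of X-linked minus median of autosomal log2 ratios (y axis) on each array of the 13 comparisons (x axis); circles and squares are the dye orientations and bars the mean of the 4 arrays. The 4 arrays of HM-1 vs B6NT lay between 0.20 and 0.41 and those of B6NT vs HM-1 NT between -0.41 and -0.22.

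Lists called in no contrast were those of mesoderm (lowest adjusted p 0.062, in HM-1 vs HM-1 NT), neuroectoderm (0.10, in HM-1 vs PDCUMNT), germ cells (0.19, in HM-1 vs B6NT), cumulus and granulosa cells (0.14, in HM-1 vs B6NT), maternally expressed imprinted genes (0.14, in HM-1 vs B6NT), genes of X inactivation or escape (0.19, in HM-1 vs PDCUMNT) and blood (0.12, in HM-1 vs PDCUMNT). Of their 70 tests 7 had an unadjusted p under 0.05. Y-linked genes and genes of the 2-cell state had 2 measured members each and mitochondrially encoded genes 0, so these lists were not tested.

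**Figure D4:**
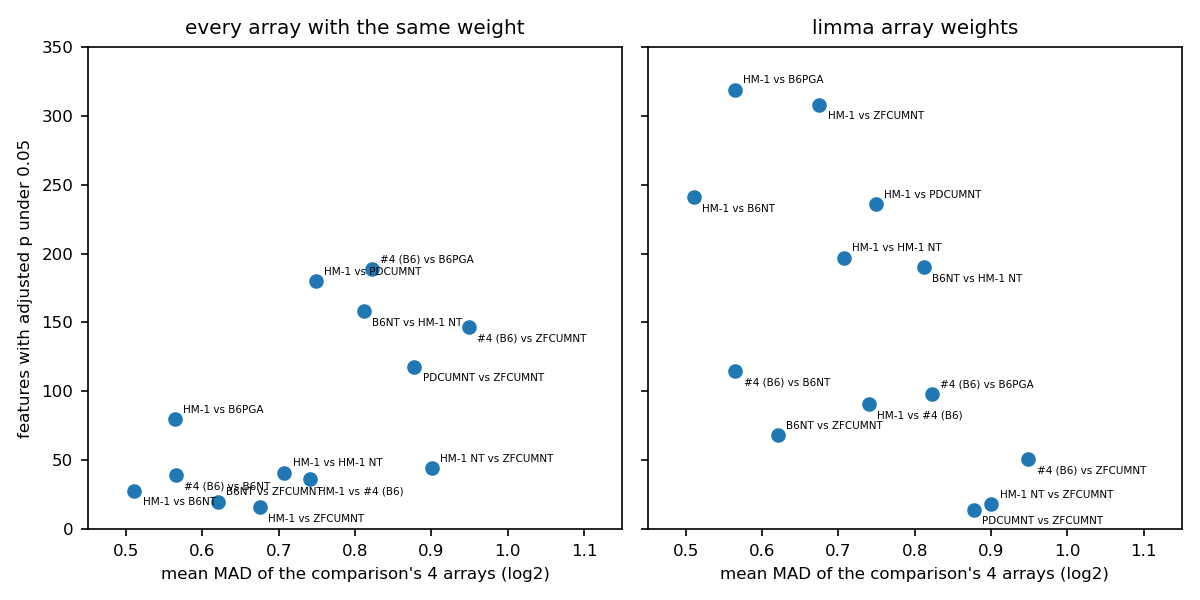
Number of features with an adjusted p under 0.05 (y axis) against the mean spread of the comparison's 4 arrays (x axis, median absolute deviation of the log2 ratios), with equal array weights (left) and with limma's array weights (right); each point is 1 of the 13 comparisons. With equal weights PDCUMNT vs ZFCUMNT had 118 calls and with array weights 14.

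Direct and indirect differences went the same way only weakly. Around the 9 triangles of comparisons, all 27 correlations across features between a direct difference and the sum of the other sides were above 0, from 0.0052 to 0.138 with a median of 0.0609; features are not independent replicates. Genes called in a direct comparison did better in part of the comparisons. The median share with the same sign in the indirect difference was 77.5% over the triangles, where random signs give an even split. It was 93.5% for HM-1 vs ZFCUMNT. Near an even split were #4 (B6) vs B6PGA (59.0%), B6NT vs ZFCUMNT (57.1%), #4 (B6) vs ZFCUMNT (56.7%), PDCUMNT vs ZFCUMNT (50.9%) and HM-1 NT vs ZFCUMNT (50.4%). The other comparisons had 67.2% to 85.7%. The share for HM-1 NT vs ZFCUMNT rests on the orientation of its arrays 1 and 3, and was 61.7% with these exchanged and 56.3% with them left out. For HM-1 vs ZFCUMNT single triangles gave 60% through HM-1 NT and 93.3% to 100% through the other lines.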

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

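The tests of spread, of fibroblast markers and of X-linked features in this part were chosen only after their results were seen; the search for values far from the rest of their group was fixed beforehand.

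Genes whose change between a line and the NT line of the same name differed between HM-1 and #4 (B6) were tested by the difference contrast, which called 30 features. The named ones were Adam3 (3.86), Ccdc80 (3.18), Igfbp3 (2.51), Lefty2 (-3.32), Shkbp1 (-3.31) and Mrps18a (-2.96).

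Among 127 groups of 4 arrays, 7 held an array far from the other 3, and chance alone picks about 1 in 20 groups. For genes these were Cfap126 in HM-1 vs HM-1 NT (4.52 on array 1, others 1.59 to 2.02), Zfp42 in HM-1 vs B6NT (-2.64 on array 3, others -3.00 to -2.97), Ogdh in #4 (B6) vs ZFCUMNT (-6.57 on array 2, others -1.76 to -0.78), and in PDCUMNT vs ZFCUMNT Bpgm (4.97 on array 1, others 1.69 to 1.89) and Spsb2 (-4.59 on array 1, others -1.29 to -0.64). Of the array measures, the spread of B6NT vs HM-1 NT array 2 was 0.695 (others 0.841 to 0.855) and HM-1 vs PDCUMNT array 1 had 75 probes at the top value (others 96 to 98).

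Fibroblast markers in HM-1 vs B6PGA had a positive value in 96.3% of the 27 measured, with medians of 0.60 to 0.94 on the 4 arrays, and 1 of the 4 other lineage lists was called, primitive endoderm (adjusted p = 6.0e-03), while mesoderm, neuroectoderm and trophectoderm were not. A trend of the ratios with residual spread is argued against, since the list had an adjusted p of 8.5e-30 after the trend was removed. The pluripotency median of -0.0225, over members going both ways, did not decide whether the undifferentiated state was lost in 1 line. The fibroblast list was also called positive in HM-1 vs HM-1 NT (median 0.36), vs #4 (B6) (0.43) and vs ZFCUMNT (0.10), but not in HM-1 vs B6NT or vs PDCUMNT. The positive shift is thus not particular to the comparison with B6PGA. RNA of fibroblasts, such as feeder cells, in unequal amounts may contribute, but the primitive endoderm call keeps it from being told apart from other differences, and a difference between the lines themselves stays open and untested. The ratios give no levels, so how many of the markers ES cells express was not measured; 1 of the 27 is held by another list.

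X-linked features were shifted in 4 of the 6 comparisons with B6NT or B6PGA, all but those with #4 (B6), and the shift in HM-1 vs B6NT was 0.25 after the trend with residual spread was removed, which argues against that trend. Unequal X chromosome dose needs shifts that add up around each triangle of comparisons; the largest gap was 2.58 standard errors with per-array means and 3.13 with medians, and 2 and 3 of 9 triangles were over 2. Means were chosen after both had been seen, because means add around a triangle and medians need not. In the 5 triangles without #4 (B6) the largest gap was 1.01 with means and 2.29 with medians. Any fixed difference between the lines adds up around a triangle in the same way. Closure therefore cannot tell an unequal dose from differences in X-linked regulation, which were not tested. An unequal dose stays open.

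More features passed in comparisons whose arrays spread more (Spearman rho 0.615 over 13 comparisons, permutation p = 0.0288; Pearson r 0.564, and 0.455 without HM-1 vs B6NT and #4 (B6) vs ZFCUMNT, the pair with the lowest and highest spread). With array weights the relation turned to a rho of -0.703 (p = 0.00925), and the share of called features with the same sign in indirect differences fell with spread (rho -0.633, p = 0.0227). With arrays 1 and 3 of HM-1 NT vs ZFCUMNT exchanged or left out that rho was -0.676 and -0.698. Without that comparison it was -0.546 (p = 0.0699), and -0.378 (p = 0.226) when its triangles were left out as well, while the other relations had a rho of 0.671 and -0.643. Larger true differences between those lines therefore stay open, since the share does not exclude them without that comparison. A single pooled spread for arrays of unequal noise is a candidate explanation of the higher counts. The turned relation with array weights does not test it, since the weights give noisier arrays less influence whether or not the lines differ more. The adjusted p over the 3 relations were 0.0288, 0.0278 and 0.0288.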

How the results depend on the processing

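Chosen only after the data were seen were the tests with top values kept, ratios not turned, arrays 1 and 3 of HM-1 NT vs ZFCUMNT left out, the line model without that comparison, the orientation of those arrays exchanged, lists with the trend removed, and array weights. For every count below the cause was not tested unless stated.

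Of 185 named gene values 183 kept their sign in every alternative that leaves the arrays oriented as labelled (136 of the 185 had a value among features measured on all 4 arrays), and 2 reversed: Cdx2 in #4 (B6) vs B6PGA was at -0.057 (adjusted p = 0.995) with each probe tested on its own, and Ipo11 in #4 (B6) vs B6NT at -0.80 with top values kept. With arrays 1 and 3 of HM-1 NT vs ZFCUMNT exchanged all 6 genes named there reversed (Dysf -0.14, Elovl7 -0.45, Slc35e3 -0.49, Slc6a13 0.52, 2900026A02Rik 2.45, Adar 0.78), and with these arrays left out only 3 of the 6 had a value. With ratios not turned 69 of the 185 reversed, so only 111 kept their sign throughout, and 5 kept sign and call. Genes named by size were chosen for 1 sign on all arrays as turned, which cancels in both of these alternatives, so neither shows which orientation is right. None kept its call in every alternative, as fits on single comparisons or averaged arrays left few calls. Of the 39 list calls the glycolysis list in HM-1 vs PDCUMNT reversed with fry (adjusted p = 0.694). Calls were also lost, 10 with fry (HM-1 vs ZFCUMNT went from 6 lists to 2), 9 with arrays averaged per comparison and 4 with an estimated correlation. No list median changed sign with medians subtracted, scaling or array weights. A fold of at least 1.5 left all counts within 1.5 times. So did the replicate block (38 in HM-1 vs HM-1 NT, 87 in PDCUMNT vs ZFCUMNT), and the numbers do not pair the arrays: 16 of 52 were closest to their own number.

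With array medians subtracted PDCUMNT vs ZFCUMNT had 67 calls (37 positive, 30 negative, against 91 and 27). The split also moved in HM-1 vs PDCUMNT (105 and 77 against 88 and 92), HM-1 vs ZFCUMNT (10 and 9 against 6 and 10), B6NT vs ZFCUMNT (9 and 10 against 15 and 5) and #4 (B6) vs ZFCUMNT (95 and 73 against 104 and 43). With arrays scaled to equal spread the counts were: HM-1 vs B6NT 332, vs B6PGA 310 (201 and 109 against 63 and 17), vs ZFCUMNT 46; B6NT vs HM-1 NT 77, vs ZFCUMNT 45; #4 (B6) vs B6NT 223, vs ZFCUMNT 23; HM-1 NT vs ZFCUMNT 5 (1 and 4 against 17 and 27), PDCUMNT vs ZFCUMNT 18 (16 and 2), shared NT 73, difference 109.

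Without a dye term the counts were: HM-1 vs HM-1 NT 22, vs #4 (B6) 21, vs B6PGA 45, vs PDCUMNT 97, vs ZFCUMNT 10, B6NT vs HM-1 NT 78, vs ZFCUMNT 6, #4 (B6) vs B6PGA 121, vs ZFCUMNT 88, HM-1 NT vs ZFCUMNT 27, PDCUMNT vs ZFCUMNT 34, shared NT 7, difference 15. Each comparison fitted alone with limma gave 0 calls in all 13 and in shared NT and 1 in the difference. The fit on 1 comparison has fewer arrays to estimate the spread. The joint fit had 642 to 2134 features at an unadjusted p under 0.05. Those of HM-1 vs #4 (B6) (642), #4 (B6) vs B6NT (716) and HM-1 vs ZFCUMNT (766) did not exceed the share of 0.05 that chance gives. Arrays averaged per comparison gave 0 in HM-1 vs HM-1 NT, HM-1 vs B6NT, B6NT vs HM-1 NT, #4 (B6) vs B6PGA, HM-1 NT vs ZFCUMNT, PDCUMNT vs ZFCUMNT and shared NT, 1 in B6NT vs ZFCUMNT, #4 (B6) vs ZFCUMNT and the difference, 2 in HM-1 vs B6PGA and #4 (B6) vs B6NT, 3 in HM-1 vs ZFCUMNT, 5 in HM-1 vs #4 (B6) and 7 in HM-1 vs PDCUMNT.

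Features measured on all 4 arrays gave 17 in HM-1 NT vs ZFCUMNT, 41 in PDCUMNT vs ZFCUMNT and 12 in shared NT, with fewer features tested. Without a filter shared NT had 35. Each probe on its own gave 25 in HM-1 vs ZFCUMNT and 62 in #4 (B6) vs B6NT. The line model gave HM-1 vs HM-1 NT 119, vs #4 (B6) 130, vs B6NT 136, vs PDCUMNT 272, vs ZFCUMNT 195, B6NT vs HM-1 NT 56, #4 (B6) vs B6NT 61, vs B6PGA 94, vs ZFCUMNT 59, HM-1 NT vs ZFCUMNT 4, PDCUMNT vs ZFCUMNT 14, shared NT 52, difference 130. With the comparison as a random block it gave, for HM-1 against HM-1 NT, #4 (B6), B6NT, B6PGA, PDCUMNT and ZFCUMNT, 136, 159, 171, 121, 342 and 229, B6NT vs HM-1 NT 76, #4 (B6) vs B6NT 69, vs B6PGA 106, vs ZFCUMNT 65, HM-1 NT vs ZFCUMNT 8, PDCUMNT vs ZFCUMNT 25, shared NT 68, difference 147.

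With top values kept the counts were B6NT vs HM-1 NT 263, #4 (B6) vs B6NT 77, vs ZFCUMNT 237 and PDCUMNT vs ZFCUMNT 182. With ratios not turned they were HM-1 vs HM-1 NT 618, vs #4 (B6) 918, vs B6NT 56, vs B6PGA 287, vs PDCUMNT 468, vs ZFCUMNT 36, #4 (B6) vs B6NT 25, vs ZFCUMNT 811, HM-1 NT vs ZFCUMNT 562, PDCUMNT vs ZFCUMNT 285, shared NT 259, difference 214; ratios not turned leave any bias shared by arrays in the estimate. Arrays 1 and 3 left out gave HM-1 NT vs ZFCUMNT 221, and their orientation exchanged gave 63 (32 positive, 31 negative), within 1.5 times of 44. The line model without that comparison gave HM-1 vs HM-1 NT 77, vs #4 (B6) 167, vs B6NT 152, vs PDCUMNT 343, vs ZFCUMNT 227, #4 (B6) vs B6NT 74, vs B6PGA 108, vs ZFCUMNT 81, PDCUMNT vs ZFCUMNT 14, shared NT 42, difference 159.

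The named genes that reversed with ratios not turned were in HM-1 vs HM-1 NT Btg3 -2.05, Pkp1 -0.74, Thnsl1 -1.85, Igfbp3 -0.19, Hmgcs1 -0.78, Rbm8a -0.12, Psma2 -0.11; in HM-1 vs #4 (B6) Rasgrp1 -0.50, Sall1 0.070, Dppa5a 0.71; in HM-1 vs B6NT Gatad1 -0.26, H4c8 0.17; in HM-1 vs B6PGA Lypla2 -1.68, Sectm1a -1.93, Dhcr7 0.13, Zfp42 0.25, Ttr -0.90, Rhox6 -2.65, Col6a2 -0.14, Hsph1 -2.06; in HM-1 vs PDCUMNT Zdhhc19 -3.41, Inf2 -0.053, Ctnnd2 1.62, Pqlc3 0.51, Zfp42 0.40, Lefty2 0.034, Hes5 -2.40, Dhcr7 0.63, Plk1 -0.82, Chac1 1.0; in HM-1 vs ZFCUMNT Fcrls -0.31, Lefty2 0.049; in B6NT vs HM-1 NT Syn2 -1.51, Fxyd4 -0.19, Tmem115 0.64, Cyth4 0.32; in B6NT vs ZFCUMNT Ndufa13 -1.91, Map3k14 -0.61, Lefty2 0.16; in #4 (B6) vs B6NT Mrps18a -0.24, Ccl3 -0.042, Klf4 -0.026, Ogfod3 2.06, Gna11 0.089, Col1a1 0.18, Timp3 0.17; in #4 (B6) vs B6PGA Tada3 -1.15, Mmp3 -0.32, Il12rb1 -0.26, Rpl36al -1.21, Ces1c 0.71, Mbtd1 0.59, Tssk2 0.30, Ccny 0.45, Uchl1 0.80, Rif1 -0.15, Cox7a2 0.29; in #4 (B6) vs ZFCUMNT Fez1 0.084; in HM-1 NT vs ZFCUMNT Dysf -0.018, Slc35e3 -0.76, Adar 1.96; in PDCUMNT vs ZFCUMNT Rnf112 -0.87, Nupr1l -0.95, Wdr54 -0.88, Mios -1.25; in shared NT Crabp1 0.29, H4c8 8.8e-04; in the difference Igfbp3 -0.22, Mrps18a 1.03.

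Array weights gave HM-1 vs HM-1 NT 197, vs #4 (B6) 91 (57 and 34 against 13 and 23), vs B6NT 241 (149 and 92 against 21 and 7), vs B6PGA 319 (176 and 143 against 63 and 17), vs ZFCUMNT 308, B6NT vs ZFCUMNT 68, #4 (B6) vs B6NT 115, vs B6PGA 98, vs ZFCUMNT 51 (23 and 28 against 104 and 43), HM-1 NT vs ZFCUMNT 18 (10 and 8 against 17 and 27), PDCUMNT vs ZFCUMNT 14, shared NT 84, difference 112.

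With 1 array left out the counts ranged as follows: HM-1 vs HM-1 NT 19 to 57, vs #4 (B6) 14 to 49, vs B6NT 16 to 47, vs B6PGA 65 to 76, vs PDCUMNT 124 to 217, vs ZFCUMNT 11 to 17, B6NT vs HM-1 NT 96 to 191, vs ZFCUMNT 9 to 34, #4 (B6) vs B6NT 31 to 35, vs B6PGA 159 to 213, vs ZFCUMNT 40 to 374, HM-1 NT vs ZFCUMNT 35 to 83, PDCUMNT vs ZFCUMNT 131 to 297, shared NT 8 to 17, difference 18 to 32. The balance of positive and negative calls turned or levelled in HM-1 vs HM-1 NT (5 and 14 without array 3, 6 and 18 without array 4), HM-1 vs #4 (B6) (7 and 7 without array 2), HM-1 vs B6NT (8 and 8 without array 3), HM-1 vs B6PGA (34 and 41 without array 3), HM-1 vs PDCUMNT (64 and 60 without array 2, but 53 and 164 without array 3 and 55 and 93 without array 4, against 88 and 92), HM-1 vs ZFCUMNT (9 and 8 without array 2), #4 (B6) vs B6PGA (64 and 96 without array 3, 72 and 87 without array 4), #4 (B6) vs ZFCUMNT(20 and 20 without array 1), HM-1 NT vs ZFCUMNT (47 and 36 without array 1, 40 and 32 without array 4) and the difference (10 and 12, 9 and 15 without array 3 or 4 of HM-1 vs HM-1 NT, 9 and 9, 15 and 15 without array 3 or 4 of #4 (B6) vs B6NT). Among counts of at least 8 with the same sign ahead, the ratio of the 2 counts moved by more than 2 times in HM-1 vs HM-1 NT (53 and 4 without array 2), HM-1 vs #4 (B6) (7 and 42 without array 3, 6 and 24 without array 4), HM-1 vs B6PGA (38 and 30 without array 4), B6NT vs ZFCUMNT (20 and 14 without array 1, 5 and 4 without array 3) and shared NT (6 and 5 without array 4 of HM-1 vs HM-1 NT, 8 and 1 without array 1 of #4 (B6) vs B6NT). The balance also turned or levelled with the line model, plain, with the random block or without HM-1 NT vs ZFCUMNT, in HM-1 vs #4 (B6) (79 and 51, 97 and 62, 99 and 68), HM-1 vs ZFCUMNT (131 and 64, 153 and 76, 148 and 79) and B6NT vs ZFCUMNT (9 and 14, 11 and 15, 12 and 15); without a dye term in B6NT vs HM-1 NT (43 and 35); with array weights in HM-1 vs PDCUMNT (124 and 112) and #4 (B6) vs B6PGA (48 and 50); with top values kept in #4 (B6) vs B6PGA (127 and 144) and HM-1 NT vs ZFCUMNT (32 and 30); with probes tested singly in HM-1 NT vs ZFCUMNT (27 and 27), without arrays 1 and 3 there (121 and 100), and without a filter in the difference (22 and 22). With ratios not turned it turned in HM-1 vs HM-1 NT (109 and 509), vs B6NT (0 and 56), vs B6PGA (15 and 272), vs ZFCUMNT (22 and 14), B6NT vs HM-1 NT (95 and 64), vs ZFCUMNT (5 and 10), #4 (B6) vs B6NT (9 and 16), HM-1 NT vs ZFCUMNT (480 and 82), shared NT (62 and 197) and the difference (26 and 188). The median correlation of direct and indirect differences, 0.0609, ranged from 0.0332 to 0.0841 over the alternatives. Only ratios are given, without signal over background, so what low signal limits was not measured.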

Other observations

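In this part only the counts of splits were fixed beforehand; the genes followed across comparisons were chosen after their values were seen.

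H4c8 was called in 6 of 6 comparisons with HM-1 (-1.28 to -0.98) and in 0 of the 7 others (-0.22 to -0.00), and its direct and indirect values around the 9 triangles of comparisons never differed by more than 1.13 standard errors. Klf4 kept its sign in 9 of 9 triangles with a largest gap of 2.00 standard errors, and it passed in #4 (B6) against HM-1, B6NT and B6PGA. Dppa5a, which also passed against ZFCUMNT, kept its sign in 9 of 9 triangles with 1 gap over 2 standard errors (2.79). Lefty2 passed in 4 of 6 comparisons with HM-1 and in 4 of 7 others, with its sign kept in 9 of 9 triangles and 2 gaps over 2 standard errors. Sall1 passed in the same comparisons as Klf4, with its sign kept in 8 of 9 triangles and 3 gaps over 2 standard errors (largest 2.99).

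Zfp42 passed in 5 of 6 comparisons with HM-1 (-2.90 to 0.24) and 1 of 7 others, with its sign kept in 7 of 9 triangles and a largest gap of 2.68. Dhcr7 passed in 4 of 6 and 1 of 7 (sign kept in 6 of 9, largest gap 4.45, 4 gaps over 2 standard errors) and Peg3 in 3 of 6 and 1 of 7 (sign kept in 5 of 9, largest gap 4.14, 3 gaps over 2). The largest gap of Zfp42, Dhcr7 and Peg3 lay in triangles that hold HM-1 NT vs ZFCUMNT, and gaps with its arrays 1 and 3 exchanged were not computed. Outside these triangles Dhcr7 had gaps of 2.63 and 3.54, and Peg3 of 2.37. On arrays 1 to 4 of HM-1 NT vs ZFCUMNT, Dhcr7 had values of 1.42, -2.72, 1.72 and -0.69, Peg3 of -1.10, 1.97, -2.09 and 0.49, and Lefty2 of -0.22, -1.69, 0.64 and -0.40. Zfp42 had -2.27, -1.35 and 1.45 on arrays 1 to 3 and was not measured on array 4.

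Each comparison was also counted with the ratios of some of its 4 arrays turned, which gives 8 splits with the real one, too few for a share under 0.05. Splits with as many calls as the real one, it included, numbered 5 in HM-1 vs HM-1 NT (real 41, highest other 286), 2 in HM-1 vs #4 (B6) (36, 113), 1 in HM-1 vs B6NT (28, 27), 2 in HM-1 vs B6PGA (80, 87), 1 in HM-1 vs PDCUMNT (180, 175), 1 in HM-1 vs ZFCUMNT (16, 2), 1 in B6NT vs HM-1 NT (158, 44), 2 in B6NT vs ZFCUMNT (20, 42), 1 in #4 (B6) vs B6NT (39, 27), 2 in #4 (B6) vs B6PGA (189, 197), 1 in #4 (B6) vs ZFCUMNT (147, 108), 5 in HM-1 NT vs ZFCUMNT (44, 76) and 2 in PDCUMNT vs ZFCUMNT (118, 123). In 8 comparisons, those of HM-1 with HM-1 NT, #4 (B6), B6NT, B6PGA and PDCUMNT and of #4 (B6) with B6NT, B6PGA and ZFCUMNT, the highest other split was the one that follows the dye, with arrays 3 and 4 turned. That split takes the 4 ratios as they stand. The 286 calls against 41 and 113 against 36 may come from a structure of the arrays that follows the dye. They may also come from ratios already turned before deposit, and the splits do not tell these readings apart. For the 8 arrays of the NT contrasts 100 splits were counted: 20 gave as many calls as the shared contrast (real 23, highest other 126) and 16 as many as the difference (real 30, highest other 167). Chance is therefore not excluded for either count, and the highest splits again leave both readings open.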
